A study of Mus musculus with 4 samples.

How the data were processed

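Ribosome-depleted total RNA from the cytosolic fraction of lipid A-stimulated mouse bone marrow-derived macrophages was sequenced from 4 biological replicates, per the labels, with 1 µg of starting RNA and a size range of 250 to 400. The labels name the same donor record for all 4 and do not say whether the replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Replicate numbers are those of the labels, and sex and age are given there as not collected.

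For each library the authors deposited a gene table, a transcript table with matching columns and a second transcript table keyed by target. The values used as counts are expected counts per gene and estimated counts per target, which need not be whole, per the file headers. TPM, a length-corrected abundance, was deposited by the authors in all of these tables. The transcript tables also hold the percent of a gene's expression in each isoform, as deposited by the authors, and these percentages were not used in a test. The text that accompanies the deposited files names mm10 and GENCODE M21 and says that the gene tables were derived from a transcriptome alignment and the target tables directly from reads. The aligner, the quantifiers and their versions are not given in the sources used here, and the column layouts are those that RSEM and kallisto write. All 55536 annotated gene identifiers matched the M21 annotation. The gene tables also list 26345 features that name no gene, of which 26248 are bare numbers, 96 are spike-in sequences and 1 is phiX. These held 0.407%, 0.224%, 0.177% and 0.0267% of the expected counts in replicates 1, 2, 3 and 4 and were left out of library sizes and tests. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart, and gene copies, pseudogenes and overlapping models share reads.

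Totals over annotated genes were 30088678, 47961117, 40282297 and 45771235 expected counts. Floors are 3 counts of a library's total, like the CPM used for levels, and they cover counting error only, since reads without molecular identifiers are not independent molecules. Expected counts were rounded to whole numbers. Genes with a mean count of at least 10 were tested, scaled by TMM in edgeR 4.0.16 under R 4.3.3. Because the deposit analysed here holds 1 group, each replicate was compared with the other 3 by edgeR's quasi-likelihood test, and calls are at a Benjamini-Hochberg adjusted p under 0.05. The lone replicate adds no residual degree of freedom, so its own spread is taken to equal that of the other 3. Standard errors were obtained from the fold and the F statistic. Variation beyond counting was tested by the deviance of a Poisson fit per gene, and the common coefficient of variation came from an intercept-only fit. Gene lists of at least 3 tested genes were tested with camera in limma 3.58.1 on log2 CPM, here counts scaled by the TMM library size, with a prior count of 2, with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over all lists and replicates. With an estimated correlation, camera rests on the few residual degrees of freedom of 1 library against 3. A list that does not pass it may therefore still differ. The spread of each list was placed among 10000 random lists matched in 20 bins of expression. Levels are list medians of log2(TPM + 1) per library, given as mean ± SD, and their differences were tested by exact two-sided sign-flip permutation. Detected means a mean of at least 1 TPM. For isoforms, the most abundant transcript of each gene was compared between both transcript tables. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

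The tests, the 25 gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The rule names a fixed set of response, receptor, macrophage and noncoding genes whatever their value, the 10 nuclear protein-coding genes with the highest mean TPM, the 3 most abundant members of each list, up to 5 genes higher and 5 lower per replicate with the largest fold among called genes with a mean of at least 1 TPM, and the 10 genes with the largest SD of log2 CPM among those with a mean count of at least 100. The text may leave out members beyond what a paragraph can carry, and the values of some list members are not reported here. Where a symbol has several gene entries, the one with the most counts stands for it in a list. Of the symbols in the lists, Norad was not matched. The lists cover immediate early, primary inflammatory, and late and interferon genes, the Toll-like receptor 4 pathway, macrophage and alternative activation genes, 9 other cell types, nuclear and cytoplasmic noncoding RNAs, ribosomal proteins, proliferation, heat shock, cholesterol synthesis, glycolysis, Y-linked genes, mitochondrially encoded genes and histones, the last taken by symbol pattern and so including a few variants made outside S phase.

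The steps were tested on simulated data drawn for 13987 genes from the real means, library sizes and the spread of replicates 2 to 4. Each gene was drawn independently, and lists were simulated with the preset correlation only. These draws therefore cannot show whether the preset correlation holds for real lists, whose members move together. For replicate 1 against the other 3, 46% of 100 genes changed 2-fold and 66% of 100 changed 4-fold were recovered, and 13.8% of calls were unchanged genes. The spread test recovered 74.5% of 200 overdispersed genes with 4.5% of its calls on Poisson genes, and the common coefficient of variation came to 0.199 where 0.2 was simulated. A list raised 1.5-fold in replicate 1 had an unadjusted camera p of 5.98e-13, and 1.5% of 200 random lists had one under 0.05.

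Alternatives were DESeq2 1.42.0 size factors and its Wald test, scaling to library totals alone, no filter and a minimum mean count of 50, leaving out mitochondrially encoded genes, gene sums of the target tables, a pseudocount of 0.1, detected members only, CPM, means for medians, a stricter 10 TPM for isoforms, and leaving out each replicate. A correction for GC content and transcript length (splines with 4 degrees of freedom per term, available for 14033 of 14041 genes), thinning of all libraries to one total, rescaling TPM without misc_RNA and ribozyme genes, and list tests on the target tables were added after the data were seen.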

Results

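RNA from the cytosolic fraction of mouse macrophages was measured 15 minutes after the cells met lipid A, at 100 ng/ml. Lipid A is the membrane anchor of bacterial lipopolysaccharide and the part that Toll-like receptor 4 recognises, and bone marrow-derived macrophages are primary cells grown out of marrow. The 4 libraries form 1 group, each labelled as a separate biological replicate of C57BL/6J mice, and were made from ribosome-depleted total RNA. No unstimulated library and no nuclear library was analysed here, so the values below are levels in stimulated cells and not responses. Replicate 1 had 30088678 expected counts on annotated genes, replicate 2 had 47961117, replicate 3 had 40282297 and replicate 4 had 45771235. A count of 0 allowed a level of up to 0.0997 CPM, a count scaled by the library total, in replicate 1 and up to 0.0626 in replicate 2, the shallowest and the deepest library, from counting error alone. Between 9751 and 10682 genes reached 1 TPM, the length-corrected abundance unit of the deposited tables, in a library.

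The libraries read as macrophage RNA. Of the 32 macrophage genes fixed before the data were examined, 31 had a mean of at least 1 TPM, against 9 of 76 markers of 9 other cell types. Lyz2, the macrophage lysozyme (chromosome 10, 117277331 to 117282321 in mm10), stood at 5100 ± 1260 TPM (SD, n = 4). The lysosomal proteases Ctsd and Ctsb stood at 4200 ± 583 and 2690 ± 574 TPM, the endosomal protein Cd68 at 748 ± 132 TPM, the growth factor receptor Csf1r at 264 ± 58.1 TPM and the surface receptor Adgre1 at 178 ± 29.8 TPM. The median macrophage gene lay 8.33 ± 0.26 above the median marker of the other types on the log2(TPM + 1) scale (SD, n = 4), above 0 in 4 of 4 libraries, and an exact two-sided sign-flip permutation gave a mean as far from 0 in 2 of its 16 sign patterns, the fewest that 4 libraries allow, so that no p under 0.05 can be reached. The size of this difference was set partly by the pseudocount, since most of the other markers lay near 0, and among members with at least 1 TPM it was 4.99.

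Detected markers of other cell types came from the T cell, B cell, neutrophil and dendritic lists. Cd28, a costimulatory receptor, was present at 85.4 ± 19.3 TPM, Il7r at 30.1 ± 2.81 TPM and Cd4 at 19.7 ± 4.93 TPM, while the T cell list as a whole had 3 of 10 members at 1 TPM or more. The B cell list had 2 of 10 detected, led by Ighm at 4.21 ± 3.29 TPM and Cd22 at 2.47 ± 0.304 TPM. The neutrophil list had 3 of 10, with the calprotectin genes S100a9 at 14.8 ± 4.89 and S100a8 at 10.3 ± 1.86 TPM and the granule gene Ngp at 2.32 ± 1.17 TPM. The dendritic list had 1 of 8 detected, Batf3 at 1.58 ± 0.804 TPM. The natural killer, erythroid, megakaryocyte, mast and basophil, and stromal lists had 0 members at that level, with library medians of log2(TPM + 1) between 0 and 0.2. Their highest single counts were 24, 7, 71, 176 and 130. The alternative activation list had 4 of 12 detected, with the transferrin receptor Tfrc at 216 ± 35.7 TPM, the lectin Clec10a at 10.3 ± 5.93 TPM and Chil3 at 3.56 ± 0.731 TPM.

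Iron storage and lysosomal genes led the protein-coding part of these libraries. The ferritin chains Ftl1 and Fth1 stood at 8800 ± 515 and 7860 ± 761 TPM (SD, n = 4), followed by Lyz2, by Psap, the precursor of the lysosomal saposins, at 4450 ± 1050 TPM, and by Ctsd and Ctsb. The glycoprotein gene Gpnmb reached 2540 ± 301 TPM, the actin gene Actb 2390 ± 977 TPM, the selenium carrier Selenop 2340 ± 1010 TPM and the actin-binding peptide gene Tmsb4x 2300 ± 859 TPM. The 7SL RNA genes Rn7s1 and Rn7s2, copies that share reads and encode the RNA of the signal recognition particle, took 57.6%, 63.3%, 60.9% and 57.1% of all TPM in replicates 1, 2, 3 and 4, but 7.43%, 11.6%, 11.3% and 8.63% of the counts. Every TPM given here from the gene tables is lowered by that share. Levels also depended on the quantification, since on the target tables Lyz2 had a mean of 1740, Ftl1 of 3070 and Fos of 65.3 TPM. Of the 25 list medians, 17 moved there by more than their SD between libraries. Mitochondrially encoded genes held 0.496%, 0.496%, 0.787% and 0.703% of the counts in replicates 1, 2, 3 and 4, or 0.62% ± 0.148 (SD, n = 4), with mt-Co1 at 1160 ± 304 TPM, mt-Nd1 at 424 ± 94.3 TPM and mt-Atp8, which overlaps its neighbour, at 1870 ± 353 TPM, and 15 of 37 members were detected. The 10 genes with the most counts in each library held 20.6% ± 3.37 of them. The 25 ribosomal protein genes were all detected, with Rplp1 at 819 ± 197, Rpl10 at 546 ± 160 and Rps24 at 520 ± 111 TPM. On the target tables these 3 genes had means of 298, 26.2 and 206 TPM, so the level of Rpl10 depended on the quantification. The 14 glycolytic genes were also all detected, among them Gapdh at 369 ± 107 and Aldoa at 195 ± 43.9 TPM.

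Immediate early genes, whose transcription needs no new protein, were abundant in the cytosol at 15 minutes, while the late cytokine genes Il6 and Ifnb1 had at most 3 counts in a library. Of 26 immediate early genes, 23 reached a mean of 1 TPM. Fos (chromosome 12, 85473890 to 85477273) stood at 161 ± 73.0 TPM (SD, n = 4), Zfp36, which encodes an RNA decay factor, at 151 ± 65.2 TPM and the transcription factor gene Junb at 109 ± 45.8 TPM. Atf3 stood at 77.5 ± 18.5 TPM, Jun at 63.8 ± 19.2 TPM, Egr1 (chromosome 18, 34859823 to 34864984) at 56.1 ± 33.9 TPM, Ier2 at 55.8 ± 31.1 TPM and the phosphatase gene Dusp1 at 39.4 ± 17.2 TPM. Il6 had 3, 1, 1 and 1 counts in replicates 1, 2, 3 and 4, Ifnb1 0, 1, 1 and 3 and the nitric oxide synthase gene Nos2 6, 28, 21 and 2.

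Of 29 primary inflammatory genes, 28 were detected. The chemokine genes Ccl3 and Ccl4 stood at 115 ± 33.7 and 86.6 ± 18.7 TPM, and Ccl7 had a mean of 88.2 ± 124 TPM that rested on replicate 1, at 274 TPM. Nfkbia, which encodes the inhibitor of NF-kB, stood at 59.2 ± 43.9 TPM, Tnf (chromosome 17, 35199381 to 35202007) at 49.3 ± 44.1 TPM, Cxcl2 at 17.4 ± 12.7 TPM and Tnfaip3 at 12.5 ± 6.98 TPM. Il1b had a mean of 7.73 ± 8.23 TPM, Nfkbiz of 5.59 ± 4.90 TPM and Cxcl1 of 3.79 ± 3.37 TPM. The spread of these genes was large, and Tnf ranged from 12.0 TPM in replicate 2 to 108 TPM in replicate 1, and Nfkbia from 23.3 TPM in replicate 2 to 114 TPM in replicate 4. The late and interferon list had 17 of 27 members detected, led by the interferon-induced genes Ifit2 at 70.6 ± 34.3 TPM and Ifit3 at 70.6 ± 23.0 TPM and by the chemokine Ccl5 at 64.2 ± 50.1 TPM, and Cxcl10 stood at 12.2 ± 5.03 TPM.

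On the log2(TPM + 1) scale, the library medians averaged 4.15 ± 0.82 for the immediate early list, 3.66 ± 0.58 for the primary inflammatory list and 2.93 ± 0.19 for the late and interferon list (SD, n = 4). The immediate early median exceeded the late one by 1.22 ± 0.93, with an exact two-sided sign-flip p of 0.25, and in replicate 2 the difference was -0.12. The primary inflammatory median exceeded the late one by 0.73 ± 0.66, above 0 in 4 of 4 libraries, with a mean as far from 0 in 2 of the 16 patterns of the same permutation. Among members with at least 1 TPM the latter difference turned to -0.31 and the former went to 0.49, a filter that leaves out 10 late, 3 immediate early and 1 primary inflammatory gene. Without replicate 4 the primary inflammatory difference was 0.47, and in CPM it was 1.20.

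The receptor complex and its signalling chain were present in every library and varied little between them. Of 31 genes of the Toll-like receptor 4 pathway, 30 were detected. The receptor gene Tlr4 (chromosome 4, 66827584 to 66930284) stood at 31.9 ± 6.91 TPM (SD, n = 4), its co-receptors Cd14 and Ly96 at 80.8 ± 27.3 TPM and between 11.6 and 21.2 TPM, the adaptors Myd88 and Ticam1 at 21.7 ± 4.48 and 7.99 ± 1.47 TPM, and the kinases Irak1 and Mapk3 at 18.0 ± 3.12 and 46.9 ± 11.2 TPM. The median member had an SD of 0.129 in TMM-scaled log2 CPM between the libraries, at percentile 4.8 of 10000 random lists matched on expression. The immediate early and primary inflammatory lists, with median SDs of 0.54 and 0.676, both stood at percentile 100.

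**Figure D1:**
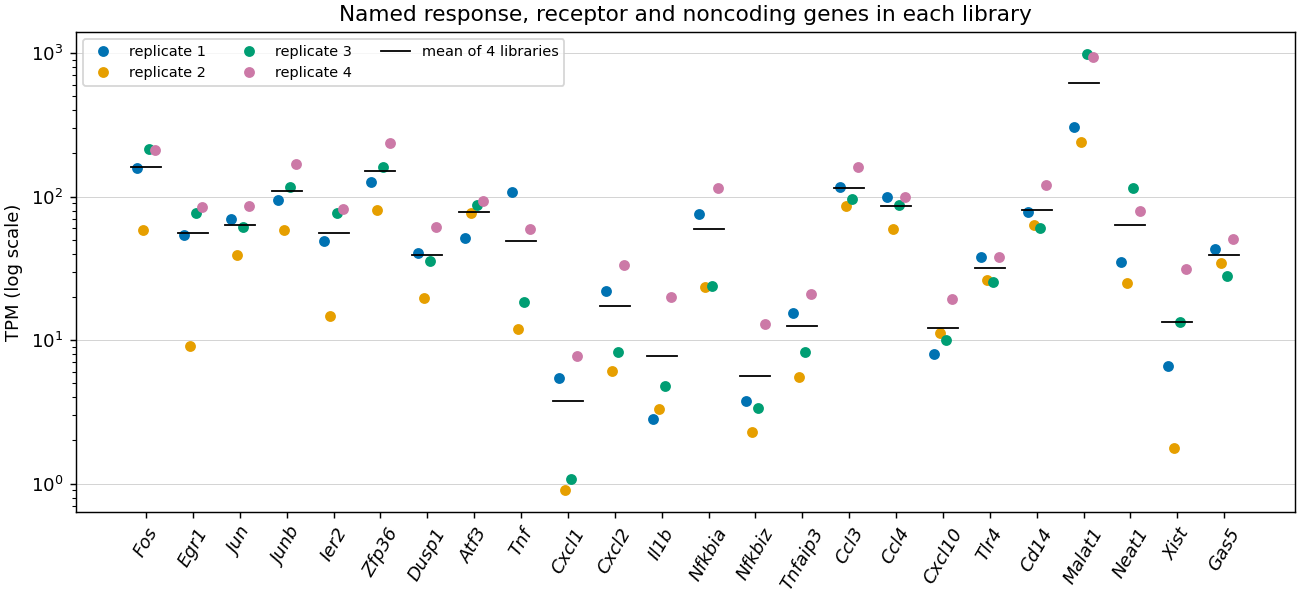
TPM of 24 named genes (log axis) in the 4 libraries, each point 1 library and each bar the mean of 4. Fos ranged from 58.5 to 216 TPM and Malat1 from 242 to 984 TPM, while Tlr4 stayed between 25.6 and 38.0 TPM.

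RNAs known to be retained in the nucleus were present in these cytosolic libraries. Malat1 (chromosome 19, 5795690 to 5802672) stood at 306, 242, 984 and 941 TPM in replicates 1, 2, 3 and 4, Neat1 at 35.1, 25.0, 115 and 79.4 TPM and Xist, the RNA of the inactive X chromosome, at 6.59, 1.77, 13.4 and 31.5 TPM. Tug1 was steadier at 19.5 ± 3.86 TPM (SD, n = 4), and 5 of the 10 nuclear noncoding RNAs reached 1 TPM. Of the 12 cytoplasmic noncoding RNAs found, 10 were detected, with 2900097C17Rik at 67.4 ± 9.52 TPM, the snoRNA host Gas5 between 28.1 and 50.9 TPM and Snhg6 at 12.9 ± 5.30 TPM. The nuclear list's median lay at -1.37 ± 0.52 relative to the cytoplasmic one on the log2(TPM + 1) scale, below 0 in 4 of 4 libraries, with a mean as far from 0 in 2 of 16 patterns of the exact sign-flip permutation. The sign of that difference depended on the unit, since it was 1.82 in CPM, which favour long transcripts, and 1.35 among members with at least 1 TPM. The 4 Y-linked genes had 0 counts in each of the 4 libraries.

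**Figure D2:**
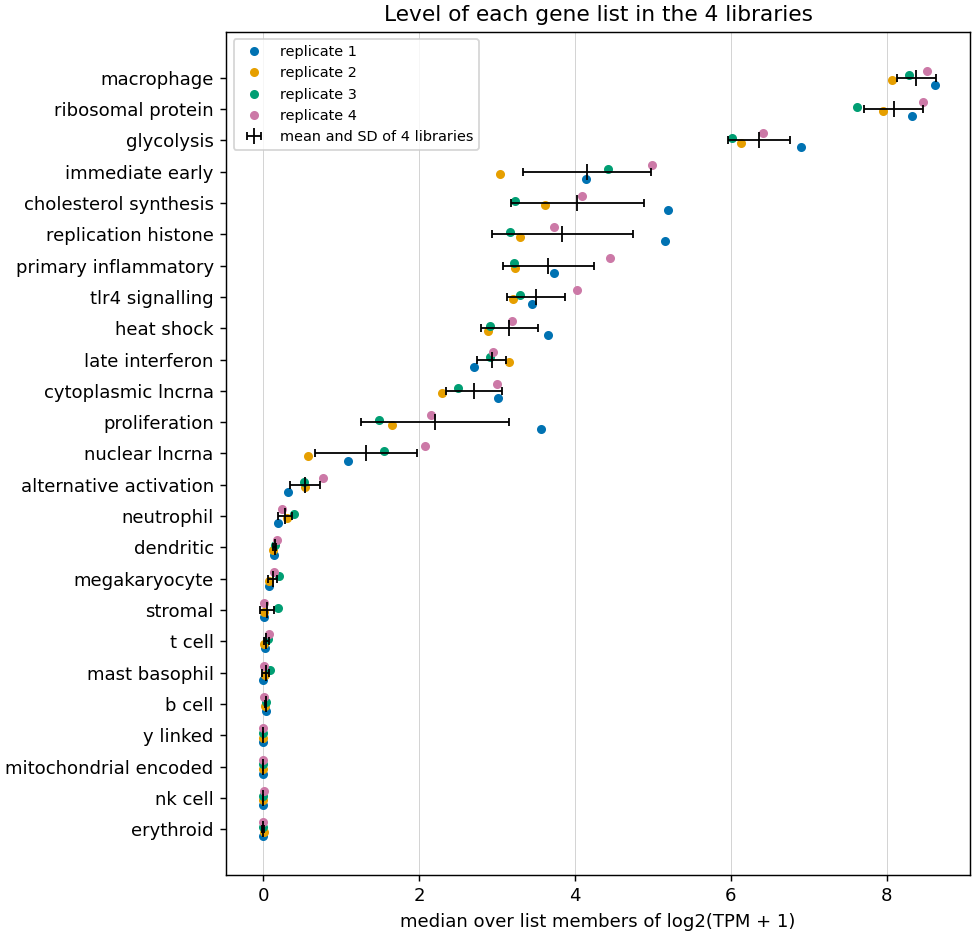
Median of log2(TPM + 1) over the members of each of 25 gene lists, with 1 point per library and the mean and SD of 4. Macrophage genes averaged 8.38 and the immediate early list 4.15, and the proliferation median stood at 3.57 in replicate 1 against 1.49 to 2.15 in the others.

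Replicate 1 had the lowest Pearson correlations with the other libraries. Pearson's r of log2(TPM + 1) across 55536 genes had a median of 0.986 over the 6 pairs and Spearman's rho a median of 0.916. Genes are not independent replicates, so no p is attached. Pairs with replicate 1 had r from 0.980 to 0.984 and the other pairs from 0.988 to 0.993. By Spearman's rho replicate 1 did not stand apart, with pairs from 0.912 to 0.920 against 0.909 to 0.928 for the others. The chi-square of each pair exceeded its degrees of freedom at least 56.0-fold, so no pair matched within counting noise. Of 14041 genes tested, 11622, or 82.8%, varied beyond Poisson counting by a deviance test with Benjamini-Hochberg adjustment, a description of biological samples at this depth, where counting noise is small. The common biological coefficient of variation from edgeR was 0.327, and 0.226 without replicate 1, when 8601 genes varied beyond counting. Among gene lists, the proliferation, histone, cholesterol synthesis, late and interferon, nuclear noncoding, mitochondrially encoded and stromal lists also reached percentile 100 of matched random lists, the heat shock list 99.5 and the neutrophil list 96.9. Percentiles were 35.3 for the macrophage list, 20.4 for ribosomal proteins, 83.3 for glycolysis, 49 for cytoplasmic noncoding RNAs and 91.5 for alternative activation. The T cell, B cell, megakaryocyte and dendritic lists stood at 92.4, 71.6, 71.4 and 61.1.

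Replicate 1 carried more RNA of cell division, histone and sterol synthesis genes than the other 3 libraries, and less of the late and interferon list. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3096 of 14041 genes differed, 2031 higher and 1065 lower. Of 21 proliferation genes, 17 were higher and 0 lower (18 higher when adjusted over the list alone), with a median log2 fold of 1.59. The replicative helicase genes were among them: Mcm5 was higher by a log2 fold of 2.98 ± 0.12 (SE), Mcm7 by 2.68 ± 0.11, Mcm6 by 2.22 ± 0.12 and Mcm3 by 2.21 ± 0.09. Rrm2, a subunit of ribonucleotide reductase, was higher by 2.70 ± 0.12, the replication clamp gene Pcna by 1.14 ± 0.13 and the mitotic kinase gene Cdk1 by 1.59 ± 0.18. The list's camera test gave an adjusted p of 1.69e-08, and adjusted p = 0.769 with an estimated correlation. The test with an estimated correlation has few residual degrees of freedom and little power here, so its values do not argue against a list. By fry, the lists that passed were proliferation, histone and B cell in replicate 1, cytoplasmic noncoding in replicate 2 and stromal in replicate 3. No other list passed fry, and those that did not include cholesterol synthesis, glycolysis, and late and interferon in replicate 1. Mcm5, Mcm7, Rrm2, Cdk1 and the other list members named for replicate 1 outside the rule for named genes were chosen after their values were seen.

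Of 65 histone genes tested, 40 were higher and 4 lower in replicate 1 (46 and 4 when adjusted over the list alone), with a median log2 fold of 1.23 and a camera adjusted p of 1.35e-09, and adjusted p = 0.639 with an estimated correlation. The linker histone genes Hist1h1a and Hist1h1b were higher by 2.04 ± 0.17 and 1.95 ± 0.10 (SE). The lower members were Hist3h2a, Hist2h2be, Hist1h1c and Hist1h2bc. The most abundant members, H3f3a at 196 ± 54.8 TPM and H3f3b at 183 ± 38.0 TPM (SD, n = 4), encode a histone variant made outside S phase and did not pass the test, with log2 folds of -0.50 and 0.04, nor did Hist2h2aa2, with 0.07. Many histone genes are near-identical copies, so their single values are uncertain.

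Of 15 cholesterol synthesis genes, 13 were higher in replicate 1 and 0 lower (14 and 0 when adjusted over the list alone), with a median log2 fold of 0.99 and a camera adjusted p of 8.68e-05, and adjusted p = 0.831 with an estimated correlation. Idi1 was higher by 1.61 ± 0.25 (SE), the squalene epoxidase gene Sqle by 1.43 ± 0.18, Msmo1 by 0.99 ± 0.17, the sterol sensor Insig1 by 0.98 ± 0.19 and Hmgcs1 by 0.87 ± 0.15. Of 14 glycolytic genes, 6 were higher (8 when adjusted over the list alone), with a median of 0.42: Pkm by 1.04 ± 0.15, Ldha, Slc2a1, Pgk1, Eno1 and Hk2. Their camera adjusted p was 0.00278, and adjusted p = 0.831 with an estimated correlation. Of 9 heat shock genes, 4 were higher (4 when adjusted over the list alone): Hsph1, Hspd1, Hsp90aa1 and Hspa8, the last by 0.65 ± 0.14.

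Members of the late and interferon list were lower in replicate 1. Of 21 late and interferon genes tested, 11 were lower and 0 higher (12 and 0 when adjusted over the list alone), with a median log2 fold of -1.04, a camera adjusted p of 3.74e-06, and adjusted p = 0.831 with an estimated correlation. The guanylate-binding protein gene Gbp5 lay at -2.26 ± 0.40 (SE), Ifit2 at -1.95 ± 0.12, the antiviral gene Rsad2 at -1.61 ± 0.21, Ifit3 at -1.14 ± 0.11, Cxcl10 at -1.01 ± 0.21 and Isg15 at -0.65 ± 0.12. Of 28 primary inflammatory genes, 2 were higher and 7 lower (3 and 8 when adjusted over the list alone). The monocyte chemokine genes Ccl7 and Ccl2 were higher by 3.11 ± 0.11 and 2.58 ± 0.25, while Il1a lay at -1.97 ± 0.33, Gadd45b at -1.74 ± 0.25 and Cd83 at -1.53 ± 0.14. Of 25 immediate early genes, Myc was higher by 2.84 ± 0.18 and Fosl2 by 0.79 ± 0.17, while Egr3 lay at -4.18 ± 0.28 and Atf3 at -1.02 ± 0.21, and the counts adjusted over the list alone were also 2 and 2. Fos, with a log2 fold of -0.10 ± 0.63, and Tnf, with 1.74 ± 0.59, did not pass.

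Macrophage and Toll-like receptor 4 pathway genes went both ways in replicate 1. The medians of all tested members were log2 folds of -0.16 and -0.1, so neither list moved far as a whole. Of 32, the scavenger receptor Msr1, Ctsl, Itgam, C1qa, the mannose receptor Mrc1 and Cx3cr1 were higher, by log2 folds of 1.70, 1.37, 1.02, 1.00, 0.86 and 2.46, and the efferocytosis receptor Mertk was lower, at -0.81 (6 higher and 2 lower when adjusted over the list alone). Of 31 Toll-like receptor 4 pathway genes, 2 were higher, among them Traf3 by a log2 fold of 0.44, and Ticam2, Ikbke, Ticam1 and Irak4 were lower, the first at -1.11 (2 and 4 when adjusted over the list alone). In the alternative activation list, Clec10a was lower, at -2.22 ± 0.18 (SE), and Cd163 higher, by 0.75 ± 0.19 (1 and 1 when adjusted over the list alone). Its camera adjusted p was 0.0234, and adjusted p = 0.831 with an estimated correlation. Of 28 tested markers of other cell types, Cd4, Cd28 and Ighm were lower and 0 higher, and 27 of the 28 log2 folds were below 0, and the counts adjusted over the list alone were also 2 lower for the T cell list and 1 lower for the B cell list. The B cell list had a camera adjusted p of 0.0259, and adjusted p = 0.831 with an estimated correlation. The 6 stromal genes among the 28 markers reached the minimum count only through replicate 3, so their low folds here were set by the filter. Selenop was lower by edgeR at -1.42 ± 0.20, and Actb, Tmsb4x and Psap did not pass, at 0.74 ± 0.23, 0.62 ± 0.16 and -1.01 ± 0.28. In the cytoplasmic noncoding list Snhg5 and Snhg6 were higher, and 0 when adjusted over the list alone. Of the mitochondrially encoded genes, mt-Co2 was higher, by 1.78 ± 0.31 (1 when adjusted over the list alone). The ribosomal protein and nuclear noncoding lists had medians of 0.04 and -1.19 and did not pass camera.

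Genes named for the largest folds above the other libraries had few counts outside replicate 1. Id1, an inhibitor of differentiation (chromosome 2, 152736251 to 152737410), had 782 counts in replicate 1 against 4, 3 and 4 in replicates 2, 3 and 4, a log2 fold of 8.14 ± 0.18 (SE) with an adjusted p of 0.000961 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The kinase gene Dmpk had 723 against 5, 12 and 15 counts, and the protease inhibitor-like gene Ctla2a 586 against 36, 28 and 30. The snRNA genes Gm26244 and Gm24924, copies with equal values, had 66 counts each in replicate 1 and 0 elsewhere, at least 29.5-fold higher against a floor of 3 counts per library. Their means over the 4 libraries were 51.9 TPM each on the gene tables, but 4.61e-09 and 1.29 TPM on the target tables. The values of this pair therefore depended on the quantification. In the other direction Lrrc14b had 3 counts against 473, 356 and 722, and the pseudogene Gm49037 had 2 against 87, 172 and 81. Gm17344, Gm38317 and Gm26602 had 0 counts in replicate 1 and were at least 28.3-fold, 8.10-fold and 6.17-fold lower.

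After a correction for GC content and transcript length, added after the data were seen, 1134 genes differed in replicate 1, of which 1121 were among the first 3096. The proliferation list had 17 higher members after it and the histone list 38 higher and 1 lower, while cholesterol synthesis went from 13 to 5, glycolysis from 6 to 1, heat shock from 4 to 1 and the late and interferon list from 11 to 8 lower. The Toll-like receptor 4 pathway went from 2 higher and 4 lower to 0 and 2, and the immediate early list from 2 and 2 to 1 and 1. Atf3, Fosl2, Isg15, Hmgcs1, Insig1, Msmo1, Hspa8, Ticam1, Cd28, Cd163, Mrc1 and Mertk were among the genes that no longer passed. Over the 3096 genes the median size of the log2 fold was 0.76 before and after the correction, while the median standard error was 0.12 before and 0.21 after. Among genes named by the rule, the calls of Hspa8, Cd28, Selenop and Snhg6 were lost without replicate 2, those of Hspa8, Snhg6, Gm26602, Gm38317 and an overlapping model of Nnt without replicate 3, and those of Snhg6, Gm26602 and Gm38317 without replicate 4. On the target tables those of Hspa8, Cd28, Ticam1, Selenop, Snhg6, Gm17344, Gm26602, Gm49037 and the Nnt model were lost, and Gm24924 changed sign.

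**Figure D3:**
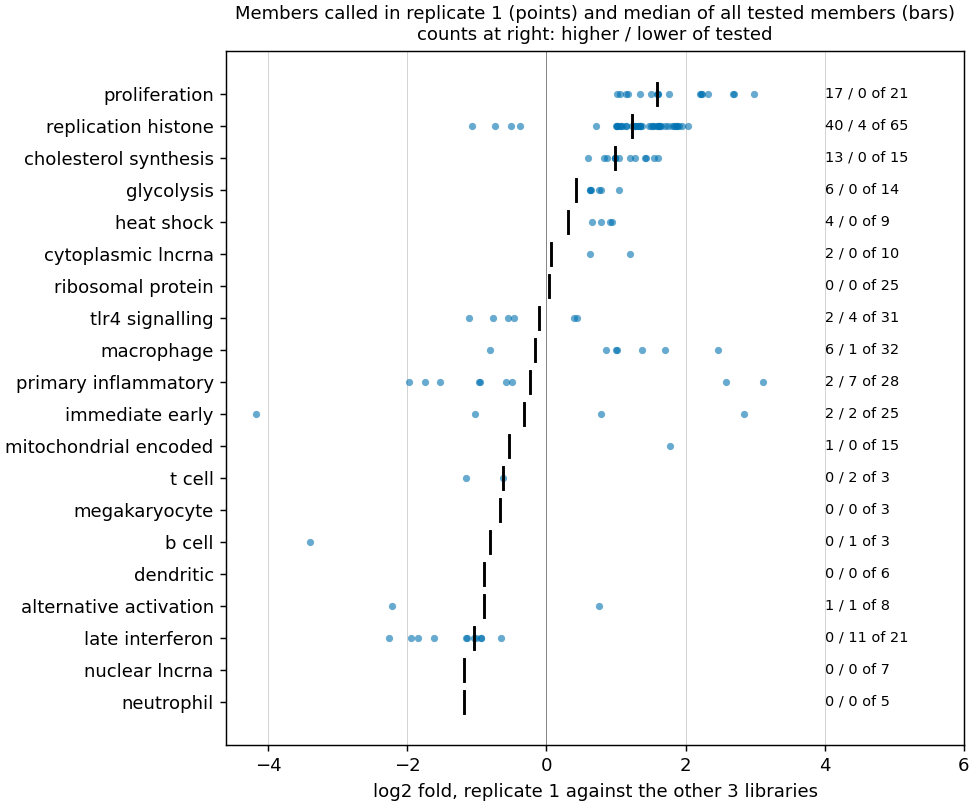
Log2 fold of replicate 1 against the other 3 libraries for each gene called by edgeR (points), the median of all tested members of 20 lists (bars), and the numbers called higher and lower of those tested. Proliferation members sat between 1.02 and 2.98 and late and interferon members between -2.26 and -0.65, and the stromal list is left out because its folds rest on counts near 0.

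Few or no genes were called in replicates 2, 3 and 4, each set against the other 3 libraries. Replicate 1 was in the reference of each of these tests and widened the residual spread. Few calls therefore do not show that replicates 2, 3 and 4 were alike. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 14041 genes differed in each of them, with 277, 135 and 104 genes at an unadjusted p under 0.05, and the DESeq2 Wald test called 8, 3 and 17. With replicate 1 left out, 86 genes differed in replicate 2, 85 of them lower. Replicate 2 had the lowest values of the nuclear noncoding and immediate early lists, with median log2 folds of -2 and -0.76 and camera adjusted p of 3.02e-05 and 8.68e-05, and adjusted p = 0.831 with an estimated correlation for each. Egr1 had 9.07 TPM there against 53.9 to 84.1 TPM elsewhere, and Ier2 14.8 against 48.7 to 82.5 TPM.

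Replicate 3 held stromal transcripts that were nearly missing elsewhere. The collagen gene Col1a2 had 130 counts in it against 6, 14 and 6 in replicates 1, 2 and 4, the chemokine gene Cxcl12 67 against 4, 4 and 1, and the proteoglycan gene Dcn 81 against 0, at least 20.2-fold higher against a floor of 3 counts per library. Of 6 stromal genes tested, edgeR called 0 over all genes and 6 higher when adjusted over the list alone, with a camera adjusted p of 1.05e-22, and adjusted p = 0.639 with an estimated correlation. Each of the 6 reached the minimum mean count of 10 only through replicate 3, so these list values rest on members that the filter chose for a high count. With no filter, 8 of the 10 stromal genes had their highest share of the counts in replicate 3. The neutrophil list had a median log2 fold of 1.53 in replicate 3, a camera adjusted p of 1.7e-09, and adjusted p = 0.831 with an estimated correlation, and 3 of its 5 tested members were higher when adjusted over the list alone. The megakaryocyte and dendritic lists had medians of 1.12 and 0.69 there, with camera adjusted p of 0.000818 and 0.0167, and adjusted p = 0.831 with an estimated correlation for each. Cholesterol synthesis and ribosomal protein genes lay at medians of -0.86 and -0.25 in replicate 3. For cholesterol synthesis the reference included replicate 1, where these genes were high. Their medians of log2(TPM + 1) were 5.19, 3.61, 3.23 and 4.09 in replicates 1, 2, 3 and 4. In replicate 4 the primary inflammatory list had a median of 0.44, a camera adjusted p of 4.79e-06, and adjusted p = 0.769 with an estimated correlation, with Il1b at 20.0 TPM against 2.81 to 4.76 elsewhere and Nfkbiz at 12.9 against 2.29 to 3.78 TPM. Over 84 tests of 21 lists in 4 replicates, 34 passed with the preset correlation, 0 with an estimated one and 5 by fry, which asks whether a list's genes move one way on balance.

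The deposited transcript tables, made by separate routes, named the same leading isoform for most list genes. Over 217 list genes with more than 1 transcript and a mean of at least 1 TPM, both tables had the same most abundant transcript for 92.4% ± 1.59 of genes (SD, n = 4), and for 185 genes it was a single transcript in both tables of all 4 libraries.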

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

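The tests of other cell types in replicate 1 and of a stronger response in replicates 3 and 4 were chosen after the result was seen, and so were the test of GC content and length, the thinning, the check that leaves out 1 member, the random lists for the second stromal list alone and the stromal counts with no filter.

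A single library far from the other 3 was found by Dixon's ratio of gap to range, set against its 95% critical value for 4 samples. It lay above that value in 20 of 157 sets of 4 values, where chance alone gives about 1 in 20, or 7.85. That figure assumes sets chosen without regard to the values, which does not hold here. Of the sets, 17 were of genes named for their fold or spread between these libraries, and 15 of the other 140 lay above the critical value, but list members were named by mean TPM, which a single high library can raise. Over all sets replicate 1 was the library apart in 10 of them, replicate 2 in 1, replicate 3 in 4 and replicate 4 in 5. Of those 10, 5 were among the 17 sets named for fold or spread. Among the other 140 sets replicate 1 was apart in 5, replicate 2 in 1, replicate 3 in 4 and replicate 4 in 5. Replicate 1 was therefore not apart more often than replicate 4 in those 140. Replicate 1 was highest in the TPM of Gm26244 and Gm24924 (a ratio of 1 each), Id1 (0.999), Dmpk (0.991), Ctla2a (0.985), Ccl7 (0.945), Mcm6 (0.941), Mcm3 (0.937), Pcna (0.864) and Hist2h2aa2 (0.844). Replicate 3 was highest in the stromal median (0.961) and in the TPM of Dcn (1), Col1a2 (0.968) and Cxcl12 (0.952). Replicate 4 was highest in the TPM of Il1b (0.887), Ctsb (0.861) and Nfkbiz (0.859), and in the natural killer median and the TPM of Ncr1 (1 each), and replicate 2 in the erythroid median (1), these last on a few counts at most. On counts scaled by the library total, 15 of the 17 genes just listed by TPM were also above the critical value and Il1b (0.791) and Ctsb (0.618) did not, and Hist2h2aa2 had replicate 4 as the lowest in place of replicate 1 as the highest (0.837).

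Signal also appeared in data that the comparisons did not use. In the target tables the processed pseudogenes Gm12895 and Gm12896, each 226 bases long on chromosome 4, had means of 2653612 and 2653902 estimated counts over the 4 libraries and took up to 9.10% of a library each, while the gene tables list them at 0. PhiX had a mean of 78606 expected counts, ranging from 12230 in replicate 4 to 122914 in replicate 1, and the features that are bare numbers had a mean of 5.

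Replicate 1 stood apart from the other 3 in 3096 genes. GC content and length bias as the whole cause is argued against by the proliferation median, a log2 fold of 1.59 before and 1.55 after the correction; over the 3096 genes the median size of the fold was 0.76 before and after while the median SE went from 0.12 to 0.21, which is why the number of calls went to 1134. Lower depth is argued against by thinning all libraries to the total of replicate 1, which called 3107 genes. Cells of the 9 other listed types were looked for in their 28 tested markers, whose median log2 fold in replicate 1 was -1.17. That median cannot decide, since many markers rest on few counts. The 6 stromal ones also passed the count filter only through replicate 3. The T cell and B cell lists, with medians of -0.62 and -0.81, were not raised in replicate 1. Only 3 of the 10 genes in each list reached the count filter. These medians therefore do not show how many such cells replicate 1 held. A difference in culture or animal stays open, since the labels name no such factor and no biological explanation was tested. Library preparation and sequencing were not tested either. The median gap between the length and effective length of long genes, which grows with fragment size, was 232.4, 215.1, 209.1 and 202.5 in replicates 1, 2, 3 and 4.

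Nuclear noncoding RNAs and immediate early genes had their lowest list medians in replicate 2 and their highest in replicates 3 and 4, and the mitochondrially encoded share of counts was also highest there (0.496%, 0.496%, 0.787% and 0.703% in replicates 1, 2, 3 and 4). More nuclear RNA in the latter may account for part of this: the share of TPM in retained-intron transcripts of other protein-coding genes was 3.02%, 2.91%, 3.89% and 4.46% in replicates 1, 2, 3 and 4, so that the lower of replicates 3 and 4 exceeded the higher of replicates 1 and 2 by 0.87 percentage points. Within immediate early genes the share was 1.11%, 1.15%, 2.68% and 3.61%, but neither share separates replicates 1 and 2, whose nuclear noncoding medians in TMM-scaled log2 CPM were 6.79 and 5.40, against 7.01 and 7.05 in replicates 3 and 4. A stronger response to lipid A in replicates 3 and 4 stays open: the primary inflammatory medians exceeded those of replicates 1 and 2 by 0.06 in TMM-scaled log2 CPM, which went to -0.33 when 1 member was left out, while the median of log2(TPM + 1) was 3.73, 3.23, 3.22 and 4.45 in replicates 1, 2, 3 and 4 and so lowest in replicate 3. No unstimulated library was analysed here.

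With no filter 8 of 10 stromal markers had their highest share of counts in replicate 3, the only library through which 6 of them reached the minimum count. The neutrophil, megakaryocyte and dendritic lists also had medians above 0 there, at log2 folds of 1.53, 1.12 and 0.69. These medians rest on 5, 3 and 6 tested members and do not establish that other cell types moved with the stromal markers. A few stromal cells among the macrophages of replicate 3 are a candidate source. In a second list written before it was looked at, 5 of 7 tested genes had their highest TMM-scaled CPM there, and Mmp2 and Serpinf1 did not. Chance gives 1 in 4 (exact one-sided binomial p of 0.0129), and with no filter 9 of 11 were highest there (exact one-sided binomial p of 0.000126). Genes measured in 1 library are not independent, so both p-values overstate the evidence. A general excess of low counts in replicate 3 is argued against by 1000 random lists matched on mean count with that second list, of which 9 had as many members highest in it (0 did for both stromal lists together, 11 of 13 genes, a count that partly restates the pattern). The levels were low, with Lox at 177, Col1a2 at 130 and Col1a1 at 111 counts in replicate 3, and Lox, Fbn1 and Fstl1 were also seen in replicates 2 and 4. Apart from cell content, no biological explanation was tested, since the labels give no factor that separates replicate 3.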

How the results depend on the processing

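The correction for GC content and length, the thinning, the rescaling without misc_RNA and ribozyme genes and the list tests on the target tables were chosen after the data were seen. The count of genes differing in replicate 1 stayed within 1.5 times of 3096 in every other setting run, from 2652 to 3361, and was 1134 (781 higher, 353 lower) after the GC and length correction, where larger standard errors ended calls. The split of higher and lower calls was 2031 to 1065, 2223 to 520 on the target tables and 1435 to 1217 without replicate 4. Without replicates 2, 3 and 4 the count ranged from 2652 to 3191. In the other replicates, where edgeR called 0, the DESeq2 Wald test called 8, 3 and 17 in replicates 2, 3 and 4, leaving out single libraries gave from 0 to 86 in replicate 2, and no filter and the GC and length correction each gave 1 in replicate 4. The coefficient of variation of 0.327 became 0.416 on the target tables and ranged from 0.226 to 0.368 with single libraries left out. The median Pearson r of 0.986 was 0.958 among genes of at least 1 TPM and 0.978 on the target tables. Of 84 list tests 34 passed, against 0 with an estimated correlation and 5 by fry. The macrophage difference of 8.33 was 11.31 with a pseudocount of 0.1, 9.98 rescaled without misc_RNA and ribozyme genes, 9.39 in CPM, 7.48 as means, 6.89 on the target tables and 4.99 among detected members. The nuclear minus cytoplasmic difference of -1.37 turned to 1.82 in CPM and 1.35 among detected members, and was -2.02 with a pseudocount of 0.1, -0.70 on the target tables and -0.22 as means. The primary inflammatory minus late difference of 0.73 turned to -0.31 among detected members and was 0.47 without replicate 4, 1.02 as means and 1.20 in CPM, and the immediate early minus late difference of 1.22 was 0.49 among detected members, 1.66 without replicate 2 and 1.81 in CPM. The share of the 10 leading genes, 20.6% of counts, was 73.4% of TPM, 25.7% on the target tables and 13.1% without misc_RNA and ribozyme genes. Leading isoforms matched for 89.4% of all genes with several. Of the named genes called in replicate 1, Gm24924 changed sign on the target tables (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p 0.455, and 0.000677 to 0.0257 in its other alternatives), and calls were lost for 9 of 32 after the GC and length correction, 9 of 30 on the target tables, and from 3 to 5 when a single library was left out, Snhg6 in each of these. The cause was not tested for these changes except where stated. Depth limits what can be said of markers with few counts, such as Ncr1, Alas2, Il6 and Ifnb1, which had under 10 counts in each library.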

Other observations

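The genes with the widest spread between the libraries, named by the fixed rule, were mostly copies and overlapping models rather than response genes. Gm49369 (chromosome 7, 142371096 to 142382667 in mm10), whose model overlaps that of Ctsd, had 1968, 45810, 49996 and 1788 counts in replicates 1, 2, 3 and 4, while Ctsd itself had 357255, 643725, 553614 and 621067. The pseudogene Gm28438 had 1874, 2035 and 2645 counts in replicates 1, 2 and 3 and 0 in replicate 4, at least 866-fold lower there against a floor of 3 counts per library. The snRNA gene Gm24497 and the pseudogenes Gm15725 and Rps12l1 were also at 0 in replicate 4, at least 96.5-fold, 93.4-fold and 51.3-fold lower. Zbed6, which lies inside another gene, was at 0 in replicate 2, at least 118-fold lower, and 1 of the overlapping models of Nnt was at 0 in replicate 1, at least 48.8-fold lower. How reads were divided among such models is uncertain, and their values are given as listed in the tables.

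Several short genes had counts in the target tables and 0 in the gene tables. Besides the pair of pseudogenes above, the 57-base microRNA genes Gm23935, Gm24270 and Gm24245, chosen after their values were seen, had equal estimated counts of 256615, 393659, 420609 and 942859 in replicates 1, 2, 3 and 4.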
